A study of Mus musculus with 4 samples.

How the data were processed

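RNA was measured in the visual cortex of wild-type C57Bl6 mice. Per the labels' protocols, 5 mice lived in darkness from birth, lost an eye on postnatal day 42, spent 4 days under a light-dark cycle and were killed on postnatal day 46. Total RNA was extracted with Trizol from cortex cut out of coronal slices, and about 10 µg per sample was turned into biotin-labelled cRNA. The cortex contralateral to the removed eye is called deprived and the ipsilateral cortex non-deprived. Per the series' design text, the tissue was pooled within each side, and 2 deprived and 2 non-deprived samples were compared. How the 5 mice were divided over the samples was not given in the sources used here, so p-values of single probe sets measure the spread between these 4 arrays.

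The deposited values are intensities on a linear scale, 1 signal per probe set, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version, the detection calls and the scaling target were not given in the sources used here. The 2% trimmed mean of the deposited intensities was about 500.3 on each array, and no value was negative. Each array held 12488 probe sets, of which 66 were controls. The annotation table of the platform gave a single gene symbol for 10855 probe sets, several for 396 and none for 1237. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table of the GRCm38.p6 assembly, which matched 10839 of the 10855, and the other 16 kept their older symbol. Probe sets with several symbols were tested but not named. No coordinates are given, because the positions of the probes were not part of the sources used here.

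Each array was scaled to the same 2% trimmed mean, 60.6 was added to each signal (the 20th percentile of the mean signals) and log2 was taken. Fold changes are therefore on the log2(signal + 60.6) scale, which understates the change of dim probe sets. Control probe sets and probe sets with a mean signal below the 40th percentile, 142.9, were left out. This kept 7458 probe sets, of which 6708 named 1 gene, for 5649 genes in all. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) compared deprived with non-deprived, two-sided, with Benjamini-Hochberg adjustment over the 7458 probe sets and a threshold of 0.05. The fit had 2 residual degrees of freedom, raised to 11.6 by the prior. The number of arrays limits the precision, and an exact permutation test of 2 arrays against 2 could not give a two-sided p under 0.333.

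A separate count took probe sets that differed at least 1.5-fold in the same direction in each of the 4 pairs of a deprived and a non-deprived array, since the design text adds cross-animal pairs to the same-numbered ones. That wording implies that arrays with the same replicate number came from the same animals. The deviations of same-numbered arrays from their group means correlated over probe sets with r = 0.27. This correlation cannot tell shared animals from shared processing of same-numbered arrays. The numbers were read as pairing the samples, mainly from the wording. The unblocked fit was kept as the main one, and a fit with the replicate number as a block was run beside it. The blocked fit left fewer residual degrees of freedom than the main fit and had 13.3 in all with its prior. Its p-values therefore rest almost wholly on the variance prior.

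Before the data were examined, 27 gene lists were fixed for activity-regulated genes, signalling, synapses, metabolism, protein synthesis and the cell types that the dissected tissue could hold. The lists share some members. Each gene was represented by its brightest probe set. camera (limma) asked whether the genes of a list shifted against all other tested genes, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists with at least 5 tested genes. At this preset, camera's p-values take their spread over genes and not over arrays. A small one is therefore no measure of how well the 4 arrays repeat each other. The calls were repeated with an estimated correlation and with fry, which asks whether the genes of a list moved on balance in 1 direction. Neither called a list.

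Named genes followed a rule fixed at the same time. It took 22 genes whatever their values, the 10 largest falls and 10 largest rises past the threshold whose arrays did not overlap between groups, and up to 4 members with the smallest p of each list called or described. Places left open were filled with probe sets at an unadjusted p under 0.01. It also took the control probe sets for the 5′, middle and 3′ parts of actin, Gapdh and the transferrin receptor. Genes named outside this rule are marked as such.

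The fit was tested on simulated data with 200 of 7458 probe sets changed, in 20 runs of 2 arrays against 2. It called 0.821% of probe sets changed by 0.5 on the log2 scale, 22.7% of those changed by 1 and 76.7% of those changed by 2, and 5.08% of the calls were false. camera with the preset correlation called a list of 18 genes lowered by 0.5 in 20 of 20 runs and 0 of 500 unshifted lists. With an estimated correlation it called the lowered list in 0 of 20 runs. Simulated probe sets varied independently, without a replicate effect and with variances drawn from limma's fitted prior. The rates of false calls therefore do not cover genes that vary together, as the ribosomal protein genes did (estimated correlation 0.394). Alternatives to the scaling, the pseudocount, the filter, the test, the thresholds and the choice of probe set were computed, as was each fit with 1 array left out.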

Results

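The data were 4 single-colour Affymetrix arrays of mouse visual cortex, 2 from deprived and 2 from non-deprived tissue. Each array gave a MAS5 signal in arbitrary units for 12488 probe sets. Median signals were 246 and 189.9 on deprived arrays 1 and 2, and 229.6 and 209.6 on non-deprived arrays 1 and 2. Deprived array 1 had the lowest mean correlation with the other 3 arrays, 0.91 over the 7458 tested probe sets, against 0.93 for each of the others. No pair of arrays shared more than 13 equal signals, so no array was a copy of another.

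The comparison asked which transcripts differ between cortex that lost the input of its main eye and cortex that kept it, when both first met light at the same time. The activity-induced transcription factors Fos and Junb were lower in the deprived cortex. Fos, an immediate-early gene that neurons switch on when they fire, fell 2.60-fold, from a signal of 3293 ± 387 to 1229 ± 174 (SD, n = 2 per group). Junb, whose protein pairs with Fos, fell 2.48-fold and 2.39-fold at its 2 probe sets. Syt1, the calcium sensor of synaptic vesicle release, fell 3.64-fold, from 3233 ± 407 to 842 ± 80.8 (n = 2 per group). In limma's fit these were log2 fold changes of -1.38 ± 0.18 (SE) for Fos, with an adjusted p of 0.020, and -1.86 ± 0.18 for Syt1, with an adjusted p of 0.0023. The Junb probe sets had adjusted p of 0.023 and 0.030.

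For 3 of the other genes past the threshold, a further probe set of the same gene was tested and did not pass. Arf3, a GTPase of membrane traffic, fell by 2.19 ± 0.29 (SE, log2) at its dimmest tested probe set (adjusted p = 0.020), while its other 2 tested probe sets gave -0.66 and 0.10. Ica1 fell by 1.43 ± 0.22 at the brighter of its 2 tested probe sets (adjusted p = 0.039), and its other probe set gave -0.34. The long noncoding RNA Norad fell by 1.29 ± 0.21 at the dimmer of 2 (adjusted p = 0.048), and its other probe set gave -0.18. Pspn, which encodes the neurotrophic factor persephin, fell by 1.99 ± 0.31 (adjusted p = 0.039), from a signal of 729 ± 59.9 to 139 ± 21.1 (SD, n = 2 per group). For Pspn, Fos and Syt1 no other probe set naming the gene alone was tested, so their falls could not be checked in this way. A further Fos probe set was too dim to test, with a mean signal of 102.

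In total 8 probe sets of 7 genes fell and 0 rose at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 405, of which 273 were lower and 132 higher, where 372.9 would be reached by chance. With the replicate number as a block, 39 fell and 1 rose, and these included all 8. That fit took its variances almost wholly from the prior, and had 690 at an unadjusted p under 0.05, of which 424 were lower and 266 higher. Leaving out deprived array 1 or 2 gave 71 or 90 probe sets and leaving out non-deprived array 1 or 2 gave 27 or 5. Pspn no longer passed without either non-deprived array (adjusted p = 0.22 and 0.24), nor did Arf3 (0.15), Norad (0.14) and the brighter Junb probe set (0.057) without non-deprived array 2. After quantile normalization Syt1 was the 1 probe set that passed (adjusted p = 0.023), with Fos at 0.059. A limma fit without the mean-variance trend called 0, with 390 at an unadjusted p under 0.05. There the 8 probe sets were far from the threshold, with adjusted p from 0.62 for Syt1 to 0.84 for Norad, and 0.73 for Fos.

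The list of immediate-early transcription factors was lower by its median and by camera's preset test. Of its 18 tested genes, 14 were lower in the deprived cortex and 4 higher, with a median log2 fold change of -0.53. Over all probe sets 2 of them fell, and 9 fell when adjusted over the list alone, among them Fos, Junb, Nr4a1, Egr2, Egr1 and Fosb. Egr2 and Nr4a1, zinc-finger and nuclear-receptor transcription factors, stood at -1.26 ± 0.22 and -1.14 ± 0.19 (SE), each with an adjusted p of 0.063 over all probe sets and 0.0038 with the block. Egr1, the brightest of the group, had a signal of 4437 ± 233 in deprived and 7004 ± 701 in non-deprived cortex (SD, n = 2 per group). Its log2 fold change was -0.65 ± 0.17, the same size as that of Fosb at -0.65 ± 0.19, and neither passed over all probe sets in limma (adjusted p = 0.40 and 0.48). camera gave the list an adjusted p of 1.0e-09, and an adjusted p of 0.36 with an estimated correlation, while fry gave 0.094. The list median lay between -0.38 and -0.66 in the 4 pairs of arrays.

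**Figure D1:**
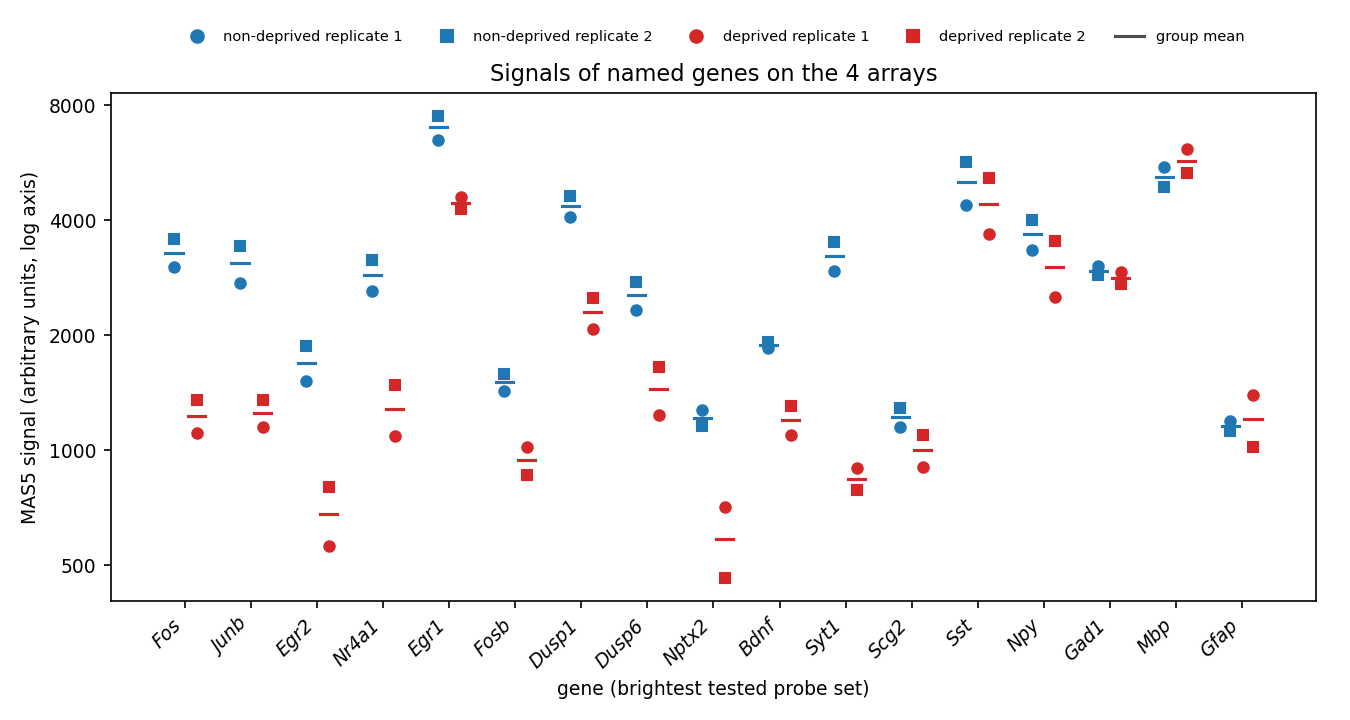
MAS5 signal (arbitrary units, log axis) of named genes on each of the 4 arrays, at the brightest tested probe set of each gene; circles are replicate 1, squares replicate 2 and bars group means. Both deprived arrays lie below both non-deprived arrays from Fos to Scg2, while the groups overlap for Sst, Npy, Gad1, Mbp and Gfap.

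Activity-regulated effector genes also shifted down, with a median of -0.28 over 29 tested genes, 25 of them lower. None fell over all probe sets, and 5 fell when adjusted over the list alone, among them Rgs4, Nptx2, Dnajb5 and Bdnf. Rgs4, a brake on G-protein signalling, had a signal of 139.8 ± 19.8 in deprived and 653 ± 125 in non-deprived cortex (SD, n = 2 per group), a log2 fold change of -1.82 ± 0.33 with an adjusted p of 0.077. Nptx2, a secreted pentraxin of excitatory synapses, was 2.01-fold lower (adjusted p = 0.23). Both passed with the block, at adjusted p of 0.016 and 0.034. The neurotrophin gene Bdnf had 1202 ± 147 in deprived and 1886 ± 53.7 in non-deprived cortex (n = 2 per group), a log2 fold change of -0.63 ± 0.18 with an adjusted p of 0.46. Homer1 and Scg2 gave -0.20 ± 0.53 and -0.28 ± 0.19, neither past the threshold. camera gave the list an adjusted p of 1.3e-07, and an adjusted p of 0.36 with an estimated correlation.

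The list of phosphatases and other feedback genes of MAP kinase signalling had a median of -0.30 over 10 genes, 8 of them lower. Dusp1 and Dusp6, phosphatases that switch MAP kinases off, were 1.88-fold and 1.75-fold lower, with adjusted p of 0.12 and 0.27 over all probe sets. These 2 fell when adjusted over the list alone, and both passed with the block (adjusted p = 0.012 and 0.032). Dusp2 and Spry4 gave -0.61 ± 0.34 and -0.57 ± 0.34. camera's adjusted p was 0.0049, and the adjusted p with an estimated correlation was 0.39.

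Neurotrophins and their receptors had a median of -0.70 over 6 tested genes. Gfra2, a receptor subunit for neurturin, was 2.38-fold lower at -1.25 ± 0.28 (SE), with an adjusted p of 0.20, or 0.017 with the block. Gfra2 and Bdnf were the 2 members that fell when adjusted over the list alone. Cntfr gave -0.77 ± 0.34, and Fgf1 -0.81 ± 0.54 but 0.030 without deprived array 2. camera's adjusted p was 0.0010, and the adjusted p with an estimated correlation was 0.39. Bdnf also stands on the list of effector genes, so these lists are not independent.

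Genes of the presynaptic terminal shifted down as a list, with a median of -0.18 over 22 tested genes, 16 of them lower. Besides Syt1, the vesicle genes Syn2, Syt11 and Cplx1 fell when adjusted over the list alone, at -0.62 ± 0.18, -0.61 ± 0.18 and -0.58 ± 0.18 (SE). None of these 3 passed over all probe sets in limma (adjusted p from 0.50 to 0.53). camera's adjusted p for the list was 3.4e-04, and the adjusted p with an estimated correlation was 0.39. The ratio of 5′ to 3′ signal of actin, a sign of RNA integrity, was 0.504 ± 0.0568 in deprived and 0.635 ± 0.0039 in non-deprived cortex (SD, n = 2 per group). That of Gapdh was 0.717 ± 0.0399 and 0.971 ± 0.136. For both genes the ratio was lower on both deprived arrays, and for the dim transferrin receptor the groups overlapped. Each of the 5 lists called lower was thus lower on the arrays with the lower ratios.

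The cytosolic ribosomal protein genes were the only list called upwards. Their median was 0.18 over 24 tested genes, 20 of them higher, and 0 passed singly, whether over all probe sets or adjusted over the list alone. Rps10, Rps18 and Rpl7 gave 0.38 ± 0.19, 0.33 ± 0.19 and 0.26 ± 0.17 (SE), and Rps4x 0.25 ± 0.18. camera's adjusted p was 0.0049, and the adjusted p with an estimated correlation was 0.81. The median was 0.013 (adjusted p = 0.71) without deprived array 2 and 0.13 (adjusted p = 0.26) without non-deprived array 1.

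**Figure D2:**
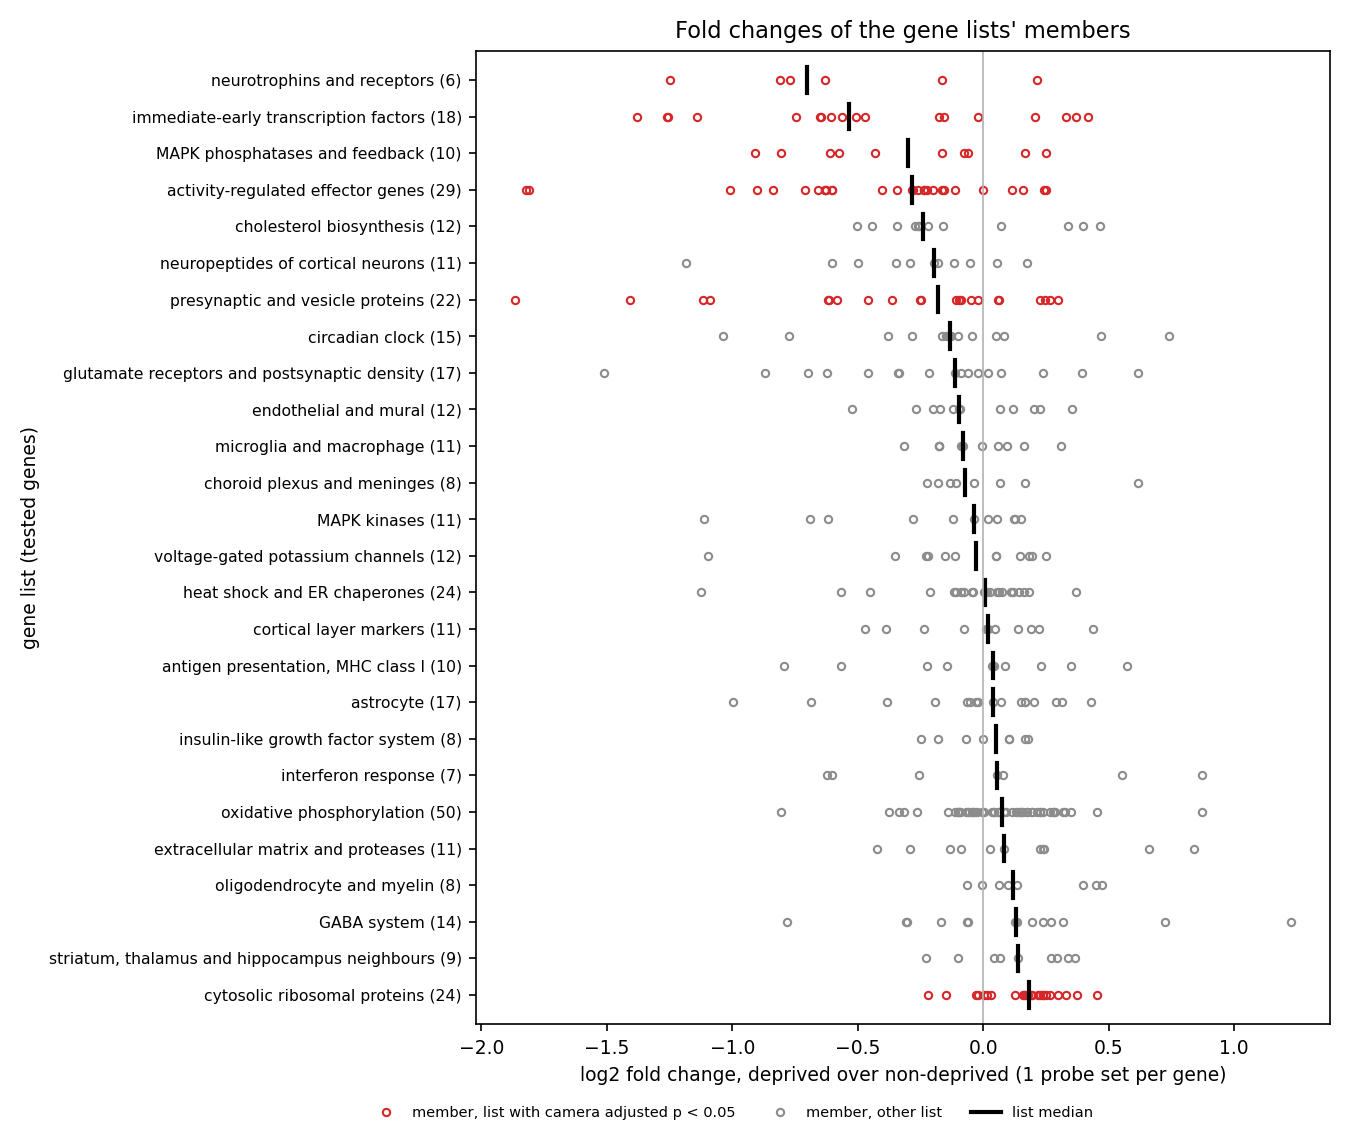
Log2 fold change, deprived over non-deprived, of each tested member (circles, 1 probe set per gene) of the 26 gene lists with at least 5 tested genes; black bars are list medians, red marks lists with a camera adjusted p under 0.05 and the number of tested genes stands in brackets. Neurotrophins and receptors have the lowest median, -0.70, and cytosolic ribosomal proteins the highest, 0.18.

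No named marker of inhibitory neurons, glia or myelin passed the threshold. Sst, Npy and Gad1 gave -0.20 ± 0.21, -0.29 ± 0.20 and -0.06 ± 0.16 (SE), and Pvalb -0.17 ± 0.17 at its brighter and 0.62 ± 0.38 at its dimmer probe set. Mbp, the myelin basic protein gene, gave 0.14 ± 0.18 at its brighter probe set and Gfap, the astrocyte filament gene, 0.04 ± 0.20, also at the brighter. The adjusted p of these 6 genes was 0.988 or above in limma at these probe sets. The lists of astrocyte, microglia, endothelial and choroid plexus genes had medians of 0.04, -0.08, -0.10 and -0.07, each with a camera adjusted p of 0.83. The list for myelin had a median of 0.12 with an adjusted p of 0.055, and Mobp gave 0.47 ± 0.17 at its brightest probe set but -0.14, -0.59 and -0.64 at the other 3. Ttr, a choroid plexus gene, was too dim to test, and for Arc, Egr4 and Vgf no probe set carried the gene's name alone.

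In all, camera called 6 of 26 lists, 5 lower and 1 higher in the deprived cortex. With an estimated correlation or with fry 0 lists were called, the lowest adjusted p being 0.36 and 0.094. The correlations estimated for the 5 lists called lower ran from -0.16 to 0.008, none above the preset 0.01. In the simulation, camera with an estimated correlation called a truly lowered list in 0 of 20 runs. Its lack of calls therefore does not show that the genes of these 5 lists varied together, and it does not decide whether they fell. Of the 20 lists not called, 15 had an adjusted p of 0.31 or more and medians from -0.24 for cholesterol biosynthesis to 0.14 for genes of the neighbouring striatum, thalamus and hippocampus. Between these lay the medians of the GABA system (0.13), antigen presentation (0.04), interferon response (0.05), heat shock and chaperones (0.01), the circadian clock (-0.13), cortical layer markers (0.02), insulin-like growth factors (0.05), extracellular matrix (0.08) and potassium channels (-0.03). The median for the neighbouring regions was 0.24 and 0.45 in the 2 pairs of arrays with deprived array 1, and -0.22 and -0.25 in those with deprived array 2. Without deprived array 2 it was 0.45 and camera called the list (adjusted p = 0.045), which over all 4 arrays had an adjusted p of 0.87 with an estimated correlation. For the astrocyte, choroid plexus, cortical layer, antigen presentation and heat shock lists the mean had the opposite sign to the median. The 3 tested red blood cell genes, too few for a test, had a median of 0.14.

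No probe set that was higher in the deprived cortex passed the adjusted threshold. The largest differences at an unadjusted p under 0.01 were 2.96-fold for Rhbdl3 and for Adcy4, an adenylyl cyclase, and 2.37-fold for Top3a, with adjusted p of 0.54, 0.53 and 0.55 in limma. Gabrd, the delta subunit of GABA-A receptors, had a signal of 437 ± 52.4 in deprived and 152 ± 29.3 in non-deprived cortex (SD, n = 2 per group), with an adjusted p of 0.49. Ndufc1, a subunit of respiratory complex I, was 1.83-fold higher with an adjusted p of 0.48, and was the 1 probe set that rose with the block (adjusted p = 0.032). Nup50, Rdh11, Tiam1, Gsn and Snw1 were 1.69-fold to 1.93-fold higher and did not pass. The other tested probe sets of Nup50, Rdh11 and Tiam1 gave -0.35, 0.09 and 0.14. Among lower signals that did not pass, Src and Tollip were 3.88-fold and 3.68-fold lower (adjusted p = 0.21 and 0.14), and both passed with the block (adjusted p = 0.047 and 0.032). The other, brighter probe set of Tollip gave 0.03 ± 0.23.

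Counted without a test, 142 probe sets differed at least 1.5-fold in the same direction in all 4 pairs of arrays, 118 lower and 24 higher in the deprived cortex. The replicate 1 arrays against the replicate 2 arrays gave 251 by the same rule, and the crossed grouping gave 50. Within the same-numbered pairs alone there were 263.

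Of the 106 probe sets that were lower at an unadjusted p under 0.01, those of 34 genes could be set beside another tested probe set of the same gene, and the rest could not. Of 33 genes outside the 3 activity lists with a probe set that was lower at an unadjusted p under 0.01 and another tested probe set, the median was -1.09 for the lower probe set and -0.073 for the 47 others, of which 7 were lower and 2 higher at an unadjusted p under 0.05. Ywhag gave -1.66 and 0.01, Vamp2 -1.20 and -0.09, and Gnai1 -1.10 and -0.07 at their 2 probe sets, whereas Gfra2 gave -1.25 and -1.56 and Camk2a -1.74 and -0.62. Both Junb probe sets fell, and the 2 tested probe sets of Klf10 gave -0.61 and -0.60, whereas those of Errfi1 gave -0.17 and -1.40. Junb was the only gene of the 3 activity lists among the 34. Probe positions were not analysed here, so the probe sets of Junb or of Klf10 may read the same part of the transcript. Their agreement is therefore no independent check. Apart from Junb, the examples of this paragraph were chosen after their values were seen.

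**Figure D3:**
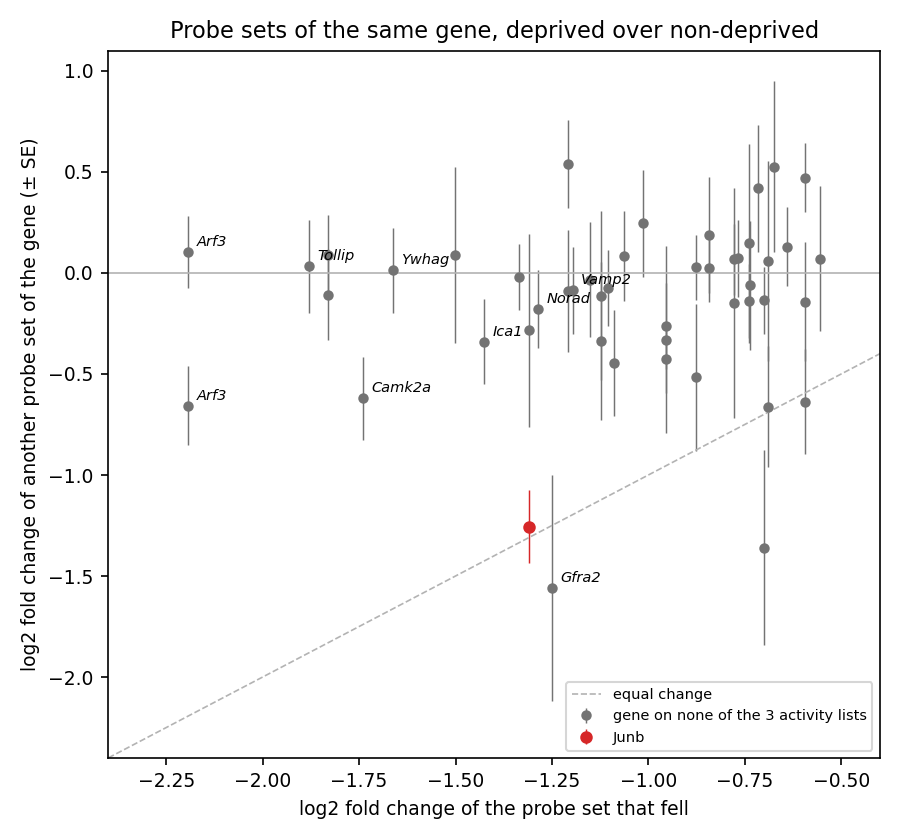
Log2 fold change, deprived over non-deprived, of another tested probe set of a gene (vertical axis, bars are SE) against that of its probe set that was lower at an unadjusted p under 0.01 (horizontal axis); the dashed line is equal change and each point is a pair of probe sets. Junb, the only gene of the activity lists shown, lies near the line, and outside the activity lists the points have a median of -0.073 on the vertical axis, with quartiles of -0.31 and 0.08.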

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

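The median of the immediate-early transcription factors stayed below 0 in every alternative run with it, from -0.36 without a filter on dim probe sets to -0.67 without non-deprived array 1, and in each of these camera called the list at its preset correlation. The count of 8 probe sets became 1 after quantile normalization, 2 with arrays scaled to a common median, 27 at an adjusted p of 0.2, and 0 both without the variance trend and with a plain test per probe set, which left 390 and 385 at an unadjusted p under 0.05. The plain test has only 2 residual degrees of freedom, at which a call over 7458 probe sets was hardly possible. Apart from this and the looser threshold, the cause was not tested. With the replicate block, which takes up differences between the replicate numbers, the count of 8 became 40. The count of 142 probe sets at 1.5-fold in all pairs became 263 in the paired arrays alone, which set fewer conditions. Besides the genes named with a blocked value, the block moved neuropeptides (adjusted p = 0.042) past the threshold and changed no other call of a list or named gene.

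The count of 142 became 80 with a pseudocount at the 40th percentile, 261 without a filter and 60 with a filter at the 60th percentile, and 30 or 639 at a fold of 2 or 1.2, as the construction of each rule implies. With 1 array left out the counts ran from 5 to 90 and from 434 to 902; these fits assume that the lone array varies like the other group, and fewer pairs had to agree. An estimated correlation and fry called 0 lists in place of 6, with lowest adjusted p of 0.36 and 0.094. Without deprived array 1 or 2, the dimmer Mbp probe set gave 0.257 or -0.264 and Fgf1 -1.65 or 0.030, where a single array decides the sign. The sign of Mbp, near 0 in the main fit, also turned without non-deprived array 1 (0.076) and with a common median. Over the named probe sets and the alternatives fitted to them, 831 values stayed on their side of the threshold, 28 no longer passed, 36 newly passed and 2 reversed. The plain test, which called 0, is not in these counts. Of the 831, 4 also turned sign, between values that both lay within 1 SE of 0. With the filter at the 60th percentile, 4 lists, the neurotrophins and 3 that were not called, and some dim named probe sets had no value. Values as deposited moved nothing, being scaled already. Dim signals limit the folds, since 60.6 is added to each.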

Other observations

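The tests of explanations in this part were chosen after the results were seen, and the fits with 1 array left out were planned before the data were examined.

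Several neuropeptide genes were lower in the deprived cortex without passing over all probe sets. Of 11 tested neuropeptide genes, 9 were lower, with a median of -0.20 and a camera adjusted p of 0.055, or 0.042 with the block (0.46 with an estimated correlation). It was 0.012 after quantile normalization and 0.035 without a filter on dim probe sets. This rested mainly on deprived array 1, since the list median was -0.40 and -0.62 in its 2 pairs with non-deprived arrays and -0.01 and -0.10 in those of deprived array 2. The median was -0.44 without deprived array 2 (adjusted p = 0.030), and the adjusted p was 0.52 without deprived array 1. Vip, a peptide of a class of interneurons, gave -1.19 ± 0.51 (SE), Adcyap1, which encodes PACAP, -0.60 ± 0.27, and Cort -0.50 ± 0.33. Glutamate receptor and postsynaptic genes lay on both sides of 0, with 12 of 17 lower and an adjusted p of 0.067, or 0.036 without that filter and 0.46 with an estimated correlation. Grin2b gave -1.51 ± 0.49, Camk2a -0.62 ± 0.21 at its brighter probe set and Gria3 -0.70 ± 0.28, whereas Dlg4, the scaffold PSD-95, gave 0.39 ± 0.16. The MAP kinase genes had a median of -0.04 over 11 genes (adjusted p = 0.067, or 0.46 with an estimated correlation). It was -0.23 without deprived array 2 (adjusted p = 0.047) and -0.01 without deprived array 1 (adjusted p = 0.52). Of these genes, Mapk9 gave -1.11 ± 0.30 and Map2k4 -0.69 ± 0.23. Oxidative phosphorylation genes had a median of 0.07 over 50 genes (adjusted p = 0.058, or 0.87 with an estimated correlation), with 31 higher, among them Ndufa5 at 0.35 ± 0.17. Their median was 0.14 without deprived array 1 (adjusted p = 7.6e-05) and -0.0015 without deprived array 2 (adjusted p = 0.80), and 0.08 without non-deprived array 2 (adjusted p = 0.0035). With the filter at the 60th percentile it was 0.09 (adjusted p = 0.033). These values come from camera's preset correlation, and the one estimated for this list was 0.31. Those estimated for the neuropeptide, glutamate receptor and MAP kinase lists were 0.032, -0.053 and -0.014. In the simulation, camera with an estimated correlation called a truly lowered list in 0 of 20 runs. Its adjusted p therefore does not decide whether the lists of this paragraph shifted.

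With the replicate number as a block, the 40 probe sets past limma's threshold included Kif5a, Kif1a, Map2 and Nsf, chosen here after their values were seen. The kinesin motor gene Kif5a fell by 1.55 on the log2 scale (adjusted p = 0.0038) and Kif1a fell by 1.08 (adjusted p = 0.017). Map2, a dendritic microtubule protein gene, fell by 1.79 (adjusted p = 0.037). Nsf, the ATPase that takes SNARE complexes apart, fell by 1.12 (adjusted p = 0.012). Without the block their adjusted p lay between 0.14 and 0.67.

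The fall of the immediate-early transcription factors, -0.53 as a median, was set against technical sources. Without deprived array 1, which stood apart from the others, it was -0.42, which argues against that array as the only source. camera still called the list there at its preset correlation. With all 4 arrays, neither an estimated correlation nor fry called the list. A weaker 5′ signal of the deprived arrays stays open. The ratios of 5′ to 3′ signal of actin and Gapdh differed by -0.34 and -0.43 on the log2 scale, and the positions of the probes were not analysed here. The 3 splits of the 4 arrays cannot give a share under 0.05; 1 of 3, the real one, gave a median this large (highest other -0.08) and 1 of 3 gave as many as 8 probe sets, against 1 for the crossed split, which also parts both pairs, and 0 for the split by replicate number, which had 693 at an unadjusted p under 0.05. Lower visual drive, other effects of eye removal and the side of the brain also stay open, since the design does not separate them.

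Falls at a single probe set of a gene, such as that of Norad, raise the question of what was measured. The other probe sets of the 33 genes had a median of -0.073 (95% bootstrap interval -0.14 to 0.03), though 7 of the 47 were lower at an unadjusted p under 0.05. That median argues against an equal fall of the whole transcript as the rule for these genes. The probe set with the smallest p of each gene was taken as the lower one, which by itself widens the gap to the others. The interval makes no allowance for this choice. Scatter of single probe sets stays open: in 1 direction the split by replicate number, which can also hold a difference between the paired samples, gave 27 such genes, while the crossed split gave 1. The weaker 5′ signal of the deprived arrays also stays open. The ratios of actin and Gapdh differed by -0.34 and -0.43 on the log2 scale, and the positions of the probes were not analysed here. No biological explanation, such as the use of another 3′ end, was tested.

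The higher ribosomal protein signals may come from deprived array 2, since the list median was 0.013 without it. Its members also varied together from array to array, with an estimated inter-gene correlation of 0.394, so that 24 genes count for far fewer independent values. Both are consistent with a difference between single arrays. An effect of deprivation was not excluded, because each group held 2 arrays.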
